A study of Mus musculus with 6 samples.

How the data were processed

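The series measured RNA of whole prefrontal cortex from 3 C57BL/6J and 3 BTBR mice on Agilent one-colour mouse arrays, 1 array per mouse, with cRNA labelled with Cy3. All mice were male, 5 months old and untreated, and RNA integrity was 9, per the labels. The design text gives 3 mice per group, so the arrays were treated as separate animals. Each array was made from 0.5 µg of RNA, per the labels' protocols.

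The deposited scanner files hold one spot's brightness per line as intensity values on a linear scale. They carry Agilent's background-subtracted signal, the mean spot signal with its local background, and flags. The images were read with Agilent Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes give version 9.1 instead, and which of these applies to the authors' matrix is not given in the sources used here. The authors' series matrix holds log2 values per probe, deposited with no statement of their scaling. Their medians were 8.82 to 8.83 on the 6 arrays and their quartiles nearly coincided between arrays. Against log2 of the scanner's processed signal, each column correlated at 0.915 to 0.929 over all probes. The steps that made the matrix remain unknown. The matrix served only as an alternative. Differences between strains correlated at 0.895 across probes well above background on all 6 arrays, with a slope of 0.549, so matrix differences were smaller.

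Log2 of the processed signal was reduced by each array's 75th percentile over its 41174 non-control probes. Spots with a non-uniformity or population outlier flag (54 to 107 per array) were left out where another spot of the probe existed, and spots of a probe were averaged. No probe was saturated on any array. A probe entered when it was well above background on at least 3 of the 6 arrays, counted without regard to strain, which left 30011 probes. Genes were named through RefSeq accessions without versions (27824 probes), current symbols (5500) or a synonym of 1 gene (380), from a table of the GRCm38.p6 assembly used for names only. Another 1083 probes kept the file's name and 6387 had no gene symbol and stayed out of the gene counts. Each gene was represented by its brightest entered probe, which gave 16482 genes. Positions are those of the 60-base probes in mm9, per the file headers.

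Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, BTBR minus C57BL/6J), with Benjamini-Hochberg adjustment over all named genes and a threshold of 0.05. Tables were handled with the data.table package, version 1.17.8. Values are mean ± SD over 3 mice, and log2 fold changes carry the standard error of the fit. Gene lists written beforehand were tested with camera at its preset inter-gene correlation of 0.01, Benjamini-Hochberg over 40 lists with at least 4 tested genes. Chromosomes were compared with Fisher's exact test, two-sided, adjusted over chromosomes. Where a gene's probes were not well above background on any array of a strain, only a bound is given. It sets the brighter strain's mean against, per array of the other strain, the higher of the probe's own signal and the lowest signal among probes well above background. Where the probe's own signal is the higher on every such array, the value is the estimated fold and not a bound. A list score is the median over a list's genes of each gene's log2 deviation from its mean over the 6 mice.

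Named genes followed a rule set before the data were examined. It took the 10 largest changes in each direction among genes past the test and well above background on all 6 arrays. It added up to 5 genes per direction measured on every array of one strain and none of the other, ranked by the bound. For each list described, it took up to 4 members with the smallest p. Every tested gene of a strain-variant list and a sex-linked list was named too. Clone, predicted and accession names were left out of the first 2 groups.

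The files show 2 slides, scanned at different times. Slide 1 held replicates 1 and 2 of each strain and slide 2 held replicate 3 of each, so results are also given with slide as a block and within slides. On slide 2, with 1 mouse per strain, there is a difference but no test.

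Between 28100 and 30665 probes per array (68.2% to 74.5%) were well above background, and the number of arrays limits the precision. On simulated data with the spread of these 16482 genes, the fit found 13.4% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 84.8% of those changed 4-fold, with 3.09% false calls. Simulated lists of 25 genes shifted by 0.3 on the log2 scale were found in 10 of 10 cases with 0 false calls among the rest, in data simulated without correlation between genes. Alternatives covered background correction, scaling, the filter on dim probes, several probes per gene, flagged and saturated spots, the authors' values, the prior, array weights, a 2-fold threshold, slide and replicate blocks, leaving out mice and other list tests. Normexp background correction added an offset of 50 to each signal, which shrinks log2 differences of dim probes by construction. The 2-fold threshold and the prior leave camera unchanged, so lists keep their calls there by construction. As no probe was saturated, leaving out saturated genes changed nothing either. Leaving out mice and adding a block leave fewer residual degrees of freedom, which by itself weakens the test, so some lost calls there follow by construction. Slide 1 alone, leaving out C57BL/6J 3 and BTBR 2 together, limma's REML array weights and, for chromosomes, alternatives other than the 2-fold threshold were chosen after seeing the data.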

Results

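Gene expression in the whole prefrontal cortex was compared between BTBR T+ Itpr3tf/J mice and C57BL/6J controls. BTBR is an inbred strain with low sociability and no corpus callosum that is used as a mouse model of autism. C57BL/6J is the common reference inbred strain. Total RNA of 3 male mice per strain, aged 5 months, was hybridised to 6 one-colour arrays. Probes well above background numbered 29977, 30178 and 30665 on the C57BL/6J arrays and 29950, 28100 and 29520 on the BTBR arrays, of 41174. The 75th percentile of the processed signal lay between 859 (BTBR 2) and 1606.7 (C57BL/6J 1). Levels below are log2 signals relative to that percentile, so 0 is the percentile itself.

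Genes with known sequence or copy-number variants between inbred strains were compared as a check on the strain labels, since the BTBR samples are titled BTBR and carry that strain as genotype, while their background field reads C57BL/6J. Of 11 tested, 5 differed, and adjusted over the list alone 4 were higher and 2 lower. Wdfy1, an endosomal adaptor protein, was 4.17-fold higher in BTBR (log2 fold change 2.06 ± 0.10 SE, limma adjusted p = 0.000225), and its 2 other probes differed by -0.26 and 1.79. Gabra2, which encodes the α2 subunit of the GABA-A receptor, was 3.11-fold higher (1.64 ± 0.23, adjusted p = 0.0117), with its other probes at 1.68 and 1.70. Nnt, the mitochondrial transhydrogenase, was 1.49-fold higher (0.58 ± 0.11, adjusted p = 0.0313), with its other probes at 0.61 and 0.62. Entpd4, a nucleotide hydrolase, was 1.99-fold lower (adjusted p = 0.00468), and Ide, the insulin-degrading enzyme, 1.89-fold lower (adjusted p = 0.00261). Glo1 (0.38, adjusted p = 0.0818), Itpr3 (-0.29, adjusted p = 0.256), Disc1 (0.19), Draxin (0.04), Alad (-0.12) and Mrps6 (0.00) did not pass the test. With normexp background correction Gabra2 (adjusted p = 0.0535) and Nnt (adjusted p = 0.104) lost their calls, with ranges over all alternatives of 0.000443 to 0.0535 and 0.00164 to 1. Gabra2 also lost its call without C57BL/6J 1 (adjusted p = 0.0534), BTBR 1 (0.0512) or BTBR 2 (0.051), and Nnt whichever mouse was left out. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background on all 6 arrays and did not differ by the test (adjusted p = 0.636, 0.168 and 0.904). Of 4 Xist probes, 1 was well above background on 1 array and the others on 0, and all mice were labelled male.

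Between the strains, 931 of 16482 genes differed (5.65%), 358 higher and 573 lower in BTBR. Of these, 348 had another entered probe. Another probe passed the test the same way in 131 of them and the opposite way in 17, while in 201 no other probe passed. The largest decreases were in Rrp7a, Ccl21a and Pttg1 and the largest increases in Cox7c, Limch1 and Serpina3n, among genes measured on all 6 arrays. At least 2-fold differences numbered 476 (175 higher, 301 lower), and at least 4-fold ones 170 (54 higher, 116 lower). In all 931 genes the values of the strains did not overlap, which selection by the test on the same values favours. Non-overlap held for 23.6% of all tested genes, where chance gives 10%. The first principal component held 47.3% of the variance and parted the strains. Of the differing genes, 61.5% were lower in BTBR. Normexp background correction called 192 genes, 72.4% of them lower, and 26 of the 71 differing genes named by rule kept their call with it. Of the genes normexp called, 191 were among the 931. Slide as a block gave 897 genes, and slide 1 alone, with 2 mice per strain and chosen after seeing the data, 971. Leaving out BTBR 1 gave 435 genes, and leaving out C57BL/6J 1, C57BL/6J 2 or BTBR 2 gave 520, 504 and 564. Without both C57BL/6J 3 and BTBR 2, which had the highest striatal marker scores, 636 genes differed, a setting chosen after seeing the data.

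Among genes measured on all 6 arrays, the largest increases in BTBR came from genes of varied function. Cox7c, a subunit of cytochrome c oxidase, rose 40.8-fold (log2 5.35 ± 0.32, adjusted p = 0.000468), from -5.64 ± 0.58 to -0.29 ± 0.32 (SD, n = 3). Limch1, an actin-associated protein, rose 21.4-fold (4.42 ± 0.15), while its 2 other probes differed by -0.13 and 0.26. Serpina3n, a secreted serine protease inhibitor made by reactive astrocytes, rose 13-fold (3.70 ± 0.23, adjusted p = 0.000539), from -1.69 ± 0.39 to 2.01 ± 0.25. The muscle myosin light chain gene Myl1 rose 10.4-fold, with its second probe at 4.20, and Cuedc1 rose 9.66-fold, with its second probe at 2.42. Wdr48, a cofactor of deubiquitinating enzymes, rose 8.92-fold, from 0.77 ± 0.11 to 3.92 ± 0.12. The axonemal dynein gene Dnah6 rose 10.3-fold, Exoc3l2 8.49-fold, Adi1 of the methionine salvage pathway 7.99-fold and the immunoglobulin gene Igh-VJ558 7.38-fold (adjusted p = 0.0457). With normexp, 5 of these 10 lost their call: Cox7c, Myl1, Dnah6, Exoc3l2 and Igh-VJ558 (adjusted p from 0.0533 to 0.439). Their log2 changes shrank there to 2.977, 2.699, 1.576, 1.759 and 2.48, in that order. Cox7c had no other entered probe. Its C57BL/6J signals (-5.33, -5.28 and -6.31) lay near the dimmest measurable signals of those arrays (-6.59, -6.67 and -6.91). For the increases with no other entered probe, Cox7c among them, a strain variant under the probe cannot be told apart from a change in RNA. Igh-VJ558, whose 4 other probes lay between 0.02 and 2.90, also lost its call whichever mouse was left out and with the slide block (adjusted p = 0.0764, range over all alternatives 0.00523 to 0.179).

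The largest decreases exceeded the largest increases in size. Rrp7a, a ribosome assembly factor, was 169-fold lower in BTBR (log2 -7.40 ± 0.18, adjusted p = 2.93e-05), whereas its other probe differed by 0.01. Ccl21a, a chemokine gene with near-identical copies, was 76.5-fold lower, falling from 3.27 ± 0.57 to -2.99 ± 0.07. Pttg1, which encodes securin, was 68.4-fold lower, falling from 3.70 ± 0.26 to -2.39 ± 0.17. The ribosomal protein gene Rpl14 was 45.4-fold lower, Galk2, a galactose kinase, 39.8-fold and Rlbp1, a retinoid-binding protein, 18.3-fold. The cytokine gene Il17d was 17.9-fold lower (-4.16 ± 0.20, adjusted p = 0.000225). Alox8, a lipoxygenase, was 12.7-fold lower, Prg4, which encodes lubricin, 12-fold and Rpusd4 11.6-fold. Rrp7a alone among these 10 had a second entered probe, and Prg4 alone lost its call with normexp (adjusted p = 0.0717, range over all alternatives 7.48e-05 to 0.0717). For the genes with 1 entered probe, a BTBR variant under it cannot be told apart from a change in RNA.

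**Figure D1:**
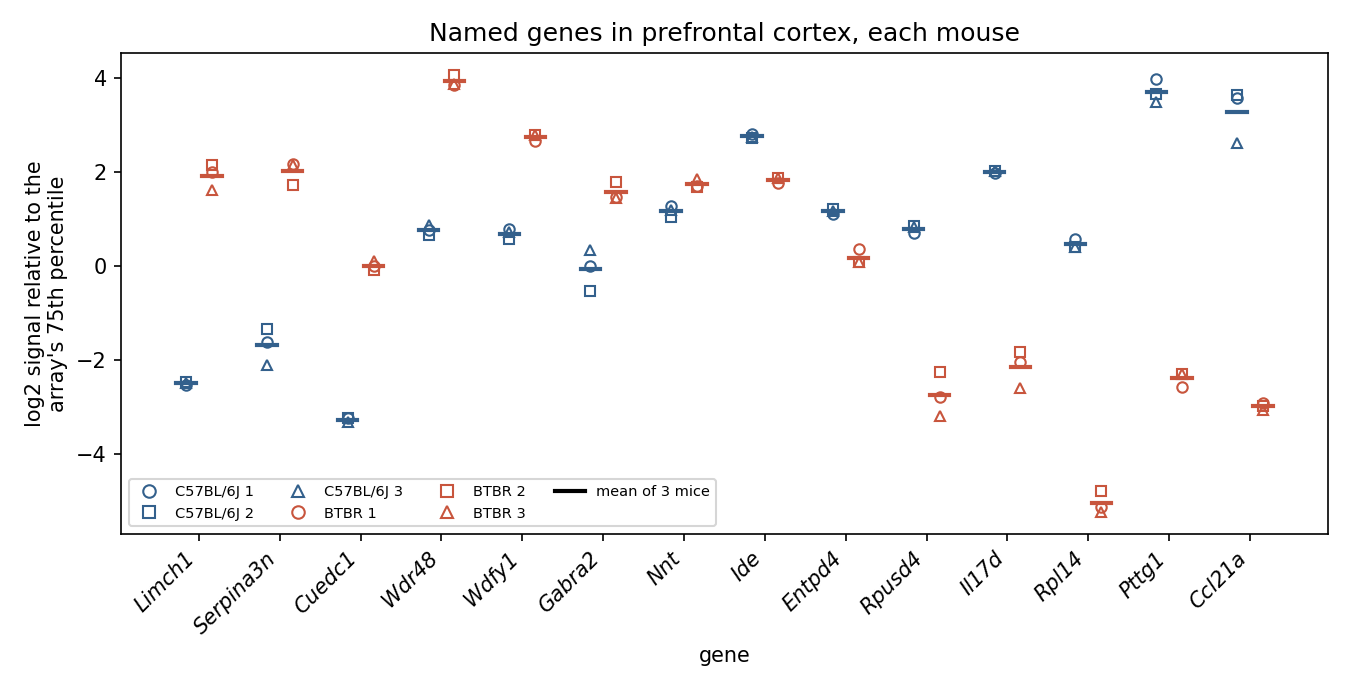
Log2 signal relative to the array's 75th percentile for 14 named genes, with 1 symbol per mouse (3 C57BL/6J in blue, 3 BTBR in red) and bars at the mean of 3 mice. The mice of the strains do not overlap in any of these genes, with Wdfy1 means of 0.69 in C57BL/6J and 2.75 in BTBR, and Pttg1 means of 3.70 and -2.39.

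Other genes were well above background on every array of one strain and on none of the other. Except for Rbm45, their folds are lower bounds against the dimmest measurable signal, or the probe's own signal where higher. Higher in BTBR were Rbm45, an RNA-binding protein (15.9-fold), and Gbp2b, a guanylate-binding protein (at least 10.4-fold). The Rbm45 value is an estimate, as its C57BL/6J signals (-6.35, -6.30 and -6.63) lay above the dimmest measurable signal of each array. Lrat, which esterifies retinol, was at least 8.02-fold higher, with its second probe at 3.27, and the granzyme gene Gzmk at least 4.13-fold. Lower in BTBR were Ckap4, an endoplasmic reticulum membrane protein (at least 106-fold), Zfp874a (at least 61.4-fold) and Trim12a (at least 51.6-fold, with its second probe at -4.88). Prim2, the large primase subunit, was at least 50.7-fold lower and Leo1 of the PAF1 transcription complex at least 20.6-fold. Adjusted p-values of these genes from limma ran from 2.93e-05 (Zfp874a and Trim12a) to 0.0041 (Gzmk). With normexp these 4 higher genes lost their call (adjusted p from 0.721 to 0.958) and these 5 lower genes kept it. Log2 differences with normexp were 1.104 for Rbm45, 0.935 for Gbp2b, 0.505 for Lrat and 0.12 for Gzmk. These lie below the folds above, which hold for the main processing only.

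Myelin genes were lower in BTBR. The oligodendrocyte and myelin list was shifted downward by camera (adjusted p = 4.7e-11), but not with the correlation between genes estimated (adjusted p = 0.936 with an estimated correlation). All 28 tested genes of the list had a lower mean, with a median log2 fold change of -0.56. Of these, 8 fell past the test over all genes and 15 when adjusted over the list alone. Mag, a myelin adhesion protein, fell 1.91-fold (-0.93 ± 0.14, adjusted p = 0.0157), Opalin 1.86-fold (-0.90 ± 0.15), Aspa, which splits N-acetylaspartate, 1.57-fold and the transcription factor Nkx6-2 1.52-fold. The list's median was -0.62 within slide 1 and -0.47 within slide 2, and the slide block gave an adjusted p of 1.14e-10. List scores were 0.26 ± 0.14 in C57BL/6J and -0.26 ± 0.11 in BTBR, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. With normexp these 4 named genes lost their calls (adjusted p from 0.0883 to 0.238), and they did too without BTBR 1 (adjusted p from 0.0654 to 0.109) or C57BL/6J 1 (from 0.0523 to 0.0597). Without C57BL/6J 2, BTBR 2, BTBR 3 and C57BL/6J 3, 1, 1, 2 and 4 of the 4 stayed. The list kept its call in 25 of 27 alternatives, some of which leave camera unchanged. It lost the call with the other list tests, camera with an estimated correlation (adjusted p = 0.936) and fry's directional test (adjusted p = 0.065). The calls of Mag, Opalin, Aspa and Nkx6-2 held in 19, 15, 16 and 15 of 25 alternatives. The oligodendrocyte precursor list was not shifted (median 0.04, 12 genes, adjusted p = 0.847), and its member Enpp6 fell 3.03-fold (adjusted p = 0.00777), a call lost with normexp (adjusted p = 0.695), the mean of its probes (0.068) and the authors' values (0.0527).

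The interferon, microglia and complement lists were shifted downward in BTBR by camera (adjusted p = 5.83e-05, 0.00159 and 0.00765), but none of these 3 was with the correlation estimated (adjusted p = 0.682, 0.936 and 0.682 with an estimated correlation). The antigen presentation list (median -0.06, adjusted p = 0.624) and the cytokine list (-0.08, adjusted p = 0.643) were not shifted. In the interferon response list, 27 of 33 genes had lower means (median -0.39), 7 fell past the test over all genes, and 17 fell and 4 rose when adjusted over the list alone. Xaf1, a proapoptotic interferon-induced gene, fell 2.81-fold (-1.49 ± 0.20, adjusted p = 0.0106), Gbp2 1.55-fold, Ifitm3 1.44-fold and Bst2 1.4-fold. In the microglia list, 6 genes fell and 1 rose among 25 (median -0.23), and 9 fell and 1 rose when adjusted over the list alone. The complement gene C1qb fell 2.16-fold (-1.11 ± 0.14, adjusted p = 0.00843) and Ptprc, the leukocyte antigen CD45, 2.61-fold, with its second probe at -0.43. Fcrls fell 2.22-fold by its brightest probe, but its second probe was at 1.55 and the mean of its probes had the opposite sign (0.20). Cx3cr1, the fractalkine receptor, rose 2.33-fold (1.22 ± 0.11, adjusted p = 0.00243), with its second probe at 0.23. In the complement list, 13 of 15 genes had lower means (median -0.27), and 3 fell over all genes and adjusted over the list alone: C1qb and C1qc (1.55-fold), also in the microglia list, and the inhibitor Cd59a (1.89-fold, second probe at 0.25).

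The medians of the interferon, microglia and complement lists were -0.47, -0.12 and -0.31 within slide 1 and -0.39, -0.38 and -0.40 within slide 2. With the slide block the adjusted p-values were 9.98e-05, 0.00223 and 0.00918. In the settings chosen after seeing the data, within slide 1 the microglia list lost its call (adjusted p = 0.118), and without C57BL/6J 3 and BTBR 2 the complement list did (adjusted p = 0.0879), against ranges over all alternatives of 8.8e-06 to 0.936 and 0.00222 to 0.682. With normexp the named genes of these lists other than Cx3cr1 and Fcrls lost their calls. The 4 interferon genes lost theirs without BTBR 1 (adjusted p from 0.0552 to 0.158), C57BL/6J 1 (from 0.0545 to 0.107) or C57BL/6J 2 (from 0.0537 to 0.143), and without BTBR 2, BTBR 3 and C57BL/6J 3, 1, 2 and 1 of the 4 stayed. Ptprc lost its call without BTBR 1 (0.0752), C57BL/6J 1 (0.0682) or C57BL/6J 2 (adjusted p = 0.0551), Cd59a without BTBR 1 (0.0702) and C1qc whichever mouse other than C57BL/6J 1 was left out (0.0546 to 0.138). Ifitm3 and Bst2 lost their calls whichever mouse was left out (adjusted p from 0.0535 to 0.146 and from 0.0723 to 0.158), and Bst2 with the slide block too (adjusted p = 0.0544). The calls of Xaf1, Gbp2, Ifitm3, Bst2, C1qb, C1qc, Cd59a and Ptprc held in 21, 13, 12, 11, 24, 14, 18 and 19 of 25 alternatives.

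Immediate early genes, which respond to neuronal activity, had higher means in BTBR in 21 of 24 cases (median 0.32, camera adjusted p = 0.00159; adjusted p = 0.936 with an estimated correlation). Nptx2, a synaptic pentraxin, rose 1.73-fold (0.79 ± 0.12, adjusted p = 0.0137) and was the sole member past the test, also when adjusted over the list alone. Its call was lost with normexp (adjusted p = 0.0591) and without C57BL/6J 2 (adjusted p = 0.0599), BTBR 1 (0.0613) or BTBR 2 (0.0503). Arc (0.85 ± 0.21, adjusted p = 0.0788), Ptgs2 (0.72) and Nr4a1 (0.42) did not pass. The median was 0.47 within slide 1 and -0.08 within slide 2, so the shift did not hold on slide 2, and the slide block gave an adjusted p of 0.00192. Ribosomal protein genes had higher means in 30 of 32 cases (median 0.17, camera adjusted p = 0.00765; adjusted p = 0.936 with an estimated correlation). Their mean was -0.02, of the opposite sign, with Rpl14 as the sole member past the test, over all genes and adjusted over the list alone. Their median was 0.24 within slide 1 and -0.04 within slide 2, and the slide block gave an adjusted p of 0.0153. Quantile normalization ended the ribosomal call (adjusted p = 0.58, range over all alternatives 2.58e-05 to 0.936), as did leaving out C57BL/6J 1 (adjusted p = 0.342) or BTBR 2 (0.124). It held in 20 of 27 alternatives.

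Shifts downward were called for 3 more lists: meningeal fibroblasts and ependyma, cholesterol synthesis, and tryptophan and kynurenine metabolism. Camera gave adjusted p = 0.0233, 0.0239 and 0.0403 for these lists, and adjusted p = 0.936 for each with an estimated correlation. The meningeal fibroblast and ependyma list had a median of -0.32 over 19 genes, with Foxj1, a regulator of motile cilia, the sole member past the test, also adjusted over the list alone (2.16-fold lower, adjusted p = 0.0363). The Foxj1 call held in 14 of 25 alternatives (adjusted p 0.00218 to 0.622) and was lost with normexp (adjusted p = 0.622) and without C57BL/6J 1 (adjusted p = 0.125), C57BL/6J 2 (0.0953), C57BL/6J 3 (0.0781), BTBR 1 (0.0825) or BTBR 2 (0.112). Quantile normalization (0.0654), no filter on dim probes (0.0695) and the authors' values (adjusted p = 0.0819) ended it too. The cholesterol synthesis list had a median of -0.14 over 20 genes, of which 2 fell, over all genes and adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, fell 2.06-fold (-1.05 ± 0.13, adjusted p = 0.00797), with its other probes at -0.58 and 0.10. The Hmgcs1 call was lost with normexp (adjusted p = 0.0537) and with the mean of its probes (0.219). Sc5d fell 1.66-fold by its brightest probe, but its second probe was at 0.94 and the mean of its probes had the opposite sign (0.11). The Sc5d call was lost with normexp (adjusted p = 0.0978) and without C57BL/6J 1 (adjusted p = 0.0636), C57BL/6J 2 (0.0637), BTBR 1 (0.0777), BTBR 2 (0.0591) or BTBR 3 (0.0522). The tryptophan and kynurenine list had a median of -0.34 over 10 genes, of which 10 had lower means, 0 passed the limma test by either adjustment and 1 had an unadjusted p under 0.05. Slide as a block gave 0.0281, 0.0218 and 0.0239. Medians were -0.32, -0.23 and -0.16 within slide 1 and -0.28, -0.01 and -0.36 within slide 2. Normexp ended the 3 calls (adjusted p = 0.0885, 0.123 and 0.12). Single mice ended them too: C57BL/6J 1 (meningeal, adjusted p = 0.0614, and cholesterol, 0.0822), C57BL/6J 2 (cholesterol, 0.126) and C57BL/6J 3 (meningeal, 0.092, and tryptophan, 0.15). BTBR 2 ended all 3 (adjusted p = 0.183, 0.0963 and 0.0963), and BTBR 3 those of cholesterol (0.0539) and tryptophan (0.0707). The calls held in 17, 19 and 12 of 27 alternatives, and another split of the 6 arrays into sets of 3 gave 11 shifted lists against 9 for the strains.

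The remaining 31 lists were not shifted (adjusted p from 0.111 to 0.991), and several held single genes that differed. Normexp, which ended the meningeal, cholesterol and tryptophan calls, called the striatal projection neuron list and 3 higher lists: presynaptic genes (median 0.15, adjusted p = 0.0069), mitochondrial respiratory chain genes (0.14, adjusted p = 8.17e-05) and glycolysis genes (0.15, adjusted p = 0.00398). The presynaptic list passed without BTBR 2 too (adjusted p = 0.0293). Excitatory cortical neuron markers had a median of 0.03, with 0 of 24 past the limma test and 2 at an unadjusted p under 0.05. The astrocyte list had a median of 0.03, and Gfap, the intermediate filament of astrocytes, fell 2.32-fold (-1.21 ± 0.18, adjusted p = 0.0154), with its other probes at -0.57 and -0.46. The Gfap call was lost with normexp (adjusted p = 0.0835) and without C57BL/6J 1 (adjusted p = 0.0584), BTBR 1 (0.0752), BTBR 2 (0.0606) or BTBR 3 (0.0516), and with the mean of its probes (-0.75, adjusted p = 0.0567). Among autism-associated genes (47 tested, median 0.06), the homeobox gene En2 fell 1.54-fold (adjusted p = 0.0229). The En2 call held in 13 of 25 alternatives (adjusted p 0.0039 to 1) and was lost with normexp (adjusted p = 0.669) and without C57BL/6J 1 (adjusted p = 0.0697), C57BL/6J 2 (0.107), BTBR 1 (0.0557), BTBR 2 (0.0827) or BTBR 3 (0.0678). In the same list Myt1l rose 1.57-fold by its brightest probe, but its other probes were between -2.32 and -0.10 and the mean of its probes had the opposite sign (-0.49). Of 38 axon guidance and callosum genes, Ntn4, a netrin, rose 4.23-fold (2.08 ± 0.15, adjusted p = 0.000968) and Sema3a fell 1.71-fold (adjusted p = 0.0457), with its second probe at -0.43. The Sema3a call was lost with the slide block (adjusted p = 0.0706) and whichever mouse was left out (adjusted p from 0.0639 to 0.142), and the Myt1l call with the slide block (adjusted p = 0.0504) and without C57BL/6J 1 (adjusted p = 0.104), C57BL/6J 2 (0.124), BTBR 1 (0.139) or BTBR 2 (0.1). Cort, the interneuron peptide cortistatin, fell 3.71-fold (-1.89 ± 0.24, adjusted p = 0.00833), and the clock gene Per3 rose 2.78-fold (1.47 ± 0.13, adjusted p = 0.00201). Normexp ended the calls of Ntn4 (log2 0.548, adjusted p = 0.923) and Per3 (log2 1.054, adjusted p = 0.17). Htr5b, a serotonin receptor, rose 3.14-fold (adjusted p = 0.0117). The Htr5b call was lost with normexp (log2 0.579, adjusted p = 0.899) and without C57BL/6J 1 (adjusted p = 0.0587), C57BL/6J 2 (0.0549) or BTBR 1 (0.0544). The Ras, ERK and mTOR list had 0 of 39 genes past the limma test (median 0.03), with 2 at an unadjusted p under 0.05. Of all named list members that differed, 8 of 43 kept their call with normexp, 15 to 36 with a single mouse left out (fewest without BTBR 1, most without C57BL/6J 3) and 14 whichever mouse was left out.

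Markers of neighbouring regions differed between single arrays of the same strain. The striatal projection neuron list scored 2.46 in C57BL/6J 3 and 0.60 in BTBR 2, and between -1.22 and -0.26 in the other 4 mice. In C57BL/6J 3 the excitatory cortical neuron list scored -0.31, the lowest of the 6. The choroid plexus list scored 2.84 in C57BL/6J 1, 0.55 in BTBR 3 and at most -0.68 elsewhere. In BTBR 2 the olfactory bulb list scored 1.54 and the red blood cell list 0.83. With all 6 mice and the main processing, these 5 lists were not shifted between the strains. The striatal list passed, lower in BTBR, without C57BL/6J 1 (adjusted p = 0.00158), C57BL/6J 2 (0.0115) or BTBR 2 (0.00565), without both C57BL/6J 3 and BTBR 2, chosen after seeing the data (0.00902), with normexp (0.0069), with no filter on dim probes (0.0324) and with every probe on its own (0.0124). The choroid plexus list passed, lower in BTBR, without C57BL/6J 2 (adjusted p = 0.0163) and within slide 1, also chosen then (0.0233), where the olfactory bulb list passed as higher (0.0121). The red blood cell list (median -0.03, adjusted p = 0.975) passed as lower in BTBR without BTBR 2 (adjusted p = 0.0215) and without both C57BL/6J 3 and BTBR 2 (0.00902). The myelin list scored 0.11, 0.39 and 0.28 in C57BL/6J 1, 2 and 3, and -0.25, -0.37 and -0.15 in BTBR 1, 2 and 3.

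**Figure D2:**
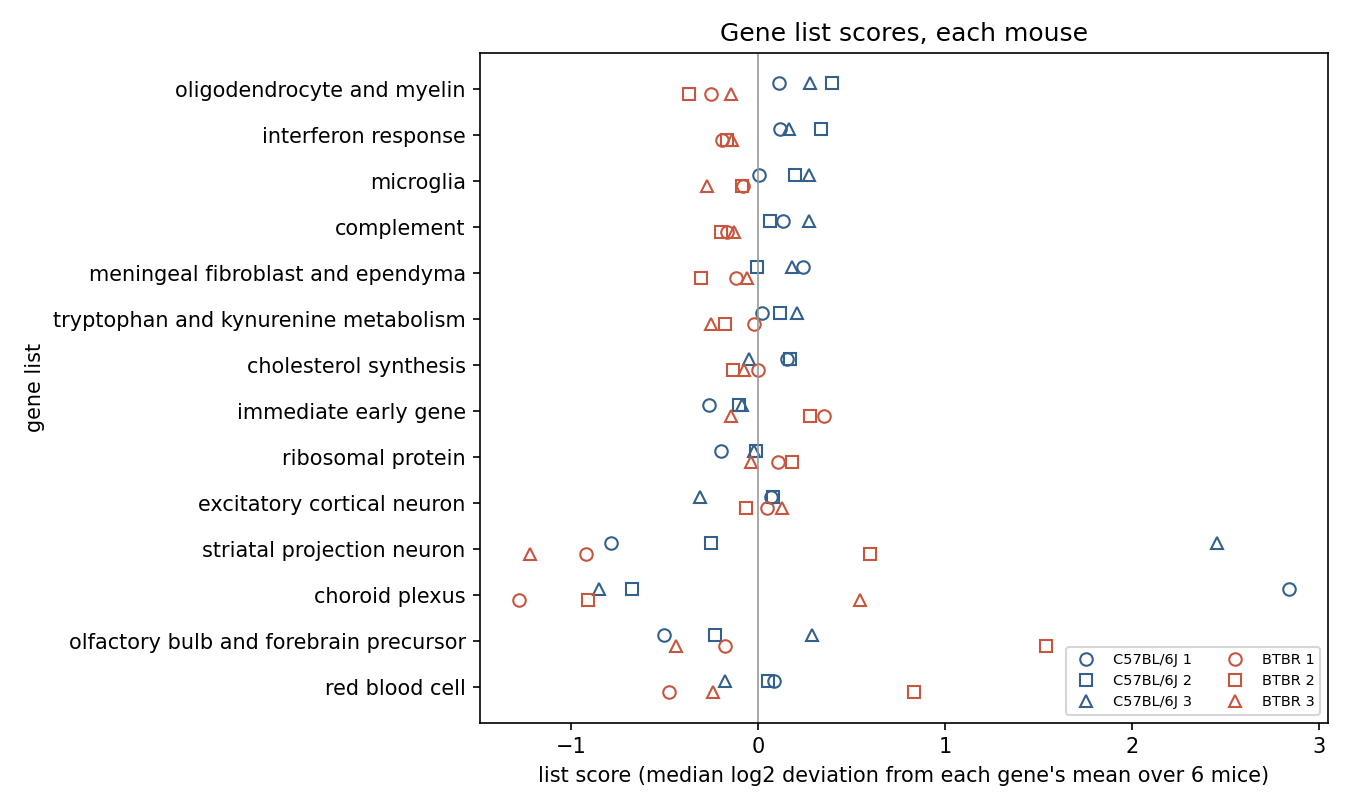
Scores of 14 gene lists on the log2 scale, with 1 symbol per mouse (C57BL/6J in blue, BTBR in red). Myelin scores lie above 0 in the 3 C57BL/6J mice and below 0 in the 3 BTBR mice, while C57BL/6J 3 stands apart in the striatal list (2.46) and C57BL/6J 1 in the choroid plexus list (2.84).

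Differing genes were spread unevenly over the chromosomes. On chromosome 13, 58 of 609 tested genes differed (9.52%, odds ratio 1.82, Fisher's exact test adjusted p = 0.00111), and on chromosome 7, 106 of 1329 did (7.98%, adjusted p = 0.00174). Chromosome 1 had 73 of 941 (7.76%, adjusted p = 0.0241). Fewer than elsewhere differed on chromosome X, with 9 of 522 (1.72%, odds ratio 0.287, adjusted p = 0.000243), and on chromosome 10, with 25 of 788 (3.17%, adjusted p = 0.00801). Positions were known for 16427 genes, of which 5.63% differed. Fisher's test takes genes as independent, but differing genes lay next to each other in 118 pairs, against 55.6 on average in permutations. The p-values per chromosome may therefore be too small. Normexp ended all 5 calls, slide as a block ended that of chromosome 1 (adjusted p = 0.0672), and within slide 1 chromosomes 13 and X kept theirs. Chromosome 1 lost its call without C57BL/6J 2 (adjusted p = 0.26) or BTBR 1 (0.106), and chromosome 10 whichever mouse was left out (range over all alternatives 0.00283 to 0.379 and 0.00231 to 0.656). The calls of chromosomes 1 and 10 held in 12 and 10 of 25 alternatives, of which the 2-fold threshold was planned for chromosomes and the others were added after seeing the data.

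**Figure D3:**
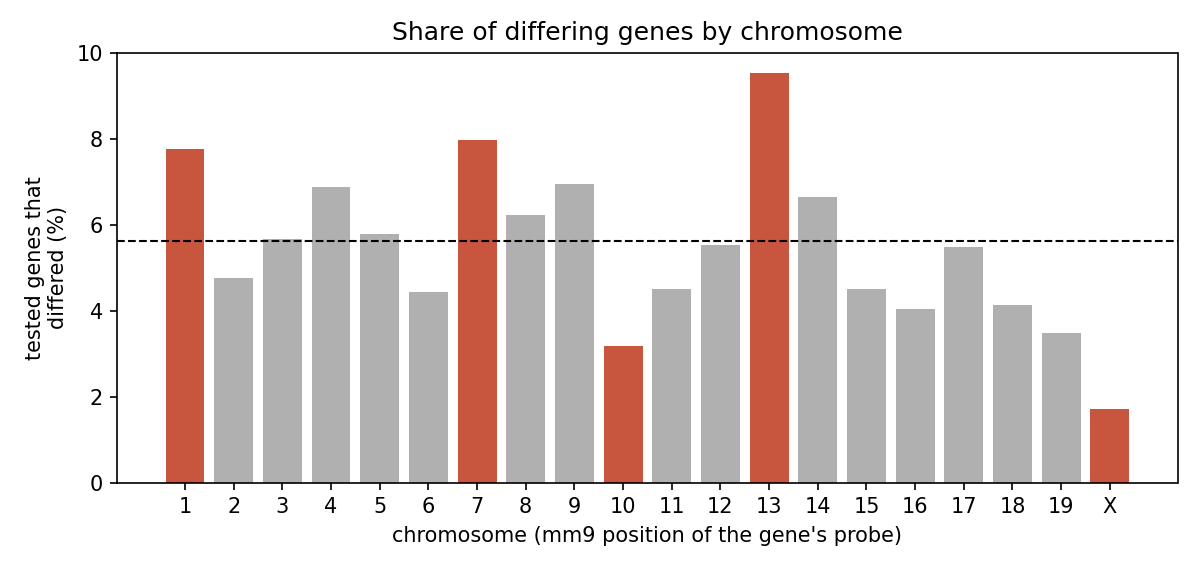
Percent of tested genes that differed between the strains, per chromosome of mm9, with red bars for chromosomes past Fisher's exact test after adjustment and grey bars for the others. The dashed line is the share over all positions (5.63%), with chromosome 13 (9.52%) highest and chromosome X (1.72%) lowest of those drawn.

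In mm9 the Wdfy1 probe lies on chromosome 1 at 79700817 to 79700876, the Gabra2 probe on chromosome 5 at 71350022 to 71350081 and the Nnt probe on chromosome 13 at 120124529 to 120124588. Serpina3n was measured on chromosome 12 at 105651918 to 105651977, Ckap4 on chromosome 10 at 83990203 to 83990262 and Rrp7a on chromosome 15 at 82946533 to 82946592. Trim12a was measured on chromosome 7 at 111448499 to 111448558 and Pttg1 on chromosome 11 at 43233801 to 43233860. Whether a probe lies in an exon or a UTR was not analysed here.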

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

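The tests of striatal tissue and of white matter for myelin genes, and of paralogs as the whole excess of neighbouring genes, were chosen after the results were seen. Probes with no gene symbol stayed outside the comparison of genes. Of 3086 that entered, 213 differed (108 higher, 105 lower in BTBR), and 10 were higher, well above background on all BTBR arrays and on no C57BL/6J array. Another 43 were lower and well above background on the C57BL/6J arrays alone.

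Large decreases outnumbered large increases, with 116 genes at least 4-fold lower and 54 at least 4-fold higher in BTBR. Under each of 4 other scalings or background corrections at least 67.6% of such genes were lower, against 68.2% here, so the choice among them did not make the split. These settings moved the median log2 difference of all genes only between -0.05 and 0.03, too little to turn a 4-fold difference around. A scaling error common to them could not be seen this way and stays open. BTBR variants under probes designed on another sequence may lower signal without a change in RNA. Of 29 genes at least 4-fold lower with another probe over 60 bases away, 51.7% had it at least 2-fold lower, against 68.8% of 16 higher genes (Fisher's exact p = 0.351), too few to decide. A strain difference in RNA stays open as well.

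Myelin genes were lower in BTBR by camera at its preset correlation, a call lost with an estimated correlation (adjusted p = 0.936) and with fry's directional test (adjusted p = 0.065; range over all alternatives 2.15e-15 to 0.936). Striatal tissue in C57BL/6J 3 is argued against, since without that mouse the median was -0.565. Probe variants are argued against too, since 17 other probes of 15 of these genes had a median of -0.58, with 15 lower. How much white matter each dissected piece held cannot be told apart from strain, since a difference within the tissue would give the same exact permutation p of 0.1. A strain difference in myelin, in mice without a corpus callosum, stays open and was not tested.

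Differing genes lay next to each other along the chromosomes in 118 pairs, where 10000 permutations within chromosomes gave 55.6 on average (permutation p = 1e-04, the smallest they can give). With neighbours sharing a symbol stem left out, 92 pairs stood against 47.4 (permutation p = 1e-04), which argues against paralogs as the whole cause, though they may account for part, as 71.5% of the excess was left. With clone-named genes left out too, 77 pairs stood against 40.4 (permutation p = 2e-04). This argues against clones lying in a neighbour's transcript as the whole cause. Paralogs that a clone had separated, such as Sp110 and Sp100, became neighbours there and were not left out again. Clones and paralogs together were therefore not tested. Of the 92 pairs, 55 moved in the same direction. Inherited blocks that differ between the strains are a candidate explanation that was not tested, as genotypes were not used here.

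The 6 arrays can be split into sets of 3 in 10 ways, too few for a share under 0.05. The strains gave 931 genes (358 higher, 573 lower) and 5 chromosomes, each the result of 1 of the 10 splits, and the highest other split gave 0. Every other split mixes the strains, so the strain difference widens the spread within its sets. With 0 genes called, 0 chromosomes follow by construction. For gene lists, 3 of the 10 splits gave at least the 9 lists of the strains, and the highest other gave 11. That split set C57BL/6J 1, BTBR 1 and BTBR 3 against the rest and does not follow the slides.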

How the results depend on the processing

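Leaving out C57BL/6J 3 and BTBR 2, slide 1 alone, REML array weights and, for chromosomes, every alternative but the 2-fold threshold were chosen after seeing the data.

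Normexp background correction gave 192 genes (53 higher, 139 lower) and 0 chromosomes. Its offset of 50 lies above the lowest signals well above background, which were 9.78 (BTBR 3) to 16.7 (C57BL/6J 1). Such an offset shrinks log2 differences of dim probes by construction, and its share in the lost calls was not tested. Leaving out a mouse and the replicate block leave fewer residual degrees of freedom, which by itself weakens the test. Any further cause there, and the cause for the array weights, was not tested. Every probe on its own, a larger number of tests by construction, gave 1632 (657 and 975), and a 2-fold threshold, stricter by construction, 476 (175 and 301). Array weights gave 1846 (802 and 1044), estimated gene by gene because limma's REML estimate stopped before it converged. The latter gave 4120 (2110 and 2010) and 2 chromosomes, as slide 1 alone did. Replicate number as a block gave 497 (193 and 304). Deviations of mice with the same number correlated across genes, which are not independent, at 0.05, -0.15 and -0.08. These values show no sign of pairing by number but cannot exclude it, and replicate 3 of each strain shared slide 2. Leaving out 1 mouse gave 435 to 900 genes (158 to 351 higher, 277 to 549 lower). The count fell by over 1.5 times without BTBR 1 (435), C57BL/6J 1 (520), C57BL/6J 2 (504) or BTBR 2 (564).

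No list (0) passed with an estimated correlation or with fry's directional test (0), where 2 and 7 had an unadjusted p under 0.05. Array signal over background limits folds to bounds, among differing genes for 14 genes below it on all C57BL/6J arrays and 52 on all BTBR arrays. The red blood cell list was not shifted with all mice (median -0.035, direction up by camera, adjusted p = 0.975). It passed as lower at -0.377 without BTBR 2 (range of medians over mice left out -0.377 to 0.306) and -0.429 without C57BL/6J 3 and BTBR 2. With the mean of a gene's probes, Fcrls (0.202), Myt1l (-0.495) and Sc5d (0.107) reversed, because their other probes had the opposite sign.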

Other observations

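Single genes of further groups differed while their lists were not shifted. Slco1c1, a thyroid hormone transporter of brain endothelium, rose 1.6-fold in BTBR (limma adjusted p = 0.00867). In the antigen presentation list H2-Bl rose 4.04-fold (adjusted p = 0.00939) and H2-T22 fell 1.83-fold (adjusted p = 0.0124, other probes at -0.89 and -0.47). Il33, a cytokine of the interleukin family, fell 1.8-fold (adjusted p = 0.0185) and the neuropeptide gene Npb 1.96-fold (adjusted p = 0.0121). Among proliferation genes Mcm3, a replication helicase subunit, rose 2.74-fold, with its second probe at 0.05, and the cyclin gene Ccnd1 fell 2.19-fold. Sdhb, a subunit of respiratory complex II, fell 1.46-fold (adjusted p = 0.0181). Of these 8 genes, H2-T22 alone kept its call with normexp background correction (adjusted p = 0.0395, range over all alternatives 0.000398 to 1), and Mcm3 alone kept its call whichever mouse was left out. The calls of Slco1c1, H2-Bl, H2-T22, Il33, Npb, Mcm3, Ccnd1 and Sdhb held in 20, 23, 20, 17, 19, 24, 20 and 15 of 25 alternatives.

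Genes of tissues outside the cortex were bright on some arrays of either strain. They were chosen after their values were seen. The pituitary hormone genes Gh and Prl had log2 signals of 1.03 and 1.79 in BTBR 3 and -0.77 and -1.65 in C57BL/6J 3. In BTBR 1 they were at -3.82 and -0.85, in BTBR 2 at -4.89 and -4.03, in C57BL/6J 1 at -5.95 and -6.42, and in C57BL/6J 2 at -6.67 and -6.25. S100a8, a neutrophil gene, was at 0.55 in BTBR 2 and between -4.42 and -2.22 in the other 5 mice. Lhx8, a transcription factor of forebrain cholinergic neurons, was at 0.20 in C57BL/6J 3 and at most -2.54 elsewhere. Of these 4 genes, 0 differed between the strains by limma (adjusted p from 0.382 to 0.846).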
